A study of Mus musculus with 3 samples.

How the data were processed

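The samples were 3 libraries from mpkDCT4a mouse cells: 1 made with an antibody against HNF1b, 1 with an antibody against H3K4me3 and 1 input. Each is the only sample of its group. Peak lists were deposited for both immunoprecipitates, and for the input none was among the lists used here. Per the submitters' processing notes, the tools were CASAVA 1.4 and MACS2 and the genome build was mm9. The version of MACS2, its settings, the control library used in peak calling and the numbers of reads are not given in the sources used here, so the depth is unknown. A q threshold appears only in the names the authors gave the peaks.

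The HNF1b list gives a position and a score per peak as deposited, and the authors' score has non-whole values whose scale (p or q value, and whether logarithmic) is not given in the sources used here. The deposited H3K4me3 list gives broad regions with a whole-number score, also of unstated scale, and the strong blocks inside each region. Blocks of 1 bp that only mark the ends of a region were not counted as strong blocks. Scores were compared only within a list, as ranks, medians, percentiles or mean log10 values; since their scale is unstated, differences in score have no unit. All features on assembled chromosomes lay within the mm9 chromosome lengths, which were taken from the UCSC table in GenomeInfoDb 1.38.1, and no features overlapped within a list. The 19 HNF1b peaks and 51 H3K4me3 regions on unassembled contigs were kept in the counts. Coordinates are printed 1-based.

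Overlap meant at least 1 shared bp, and the number of overlapping peaks was checked with bedtools 2.31.1. Each share was set beside 1000 seeded random placements of the HNF1b peaks that kept every peak on its chromosome and kept its width, with peaks on contigs left in place. Assembly gaps and unmappable bases were not excluded from placement, which lowers random overlap. The ratio is the observed share over the mean of the placements, and an alternative was said to keep a result when the observed share stayed outside the central 95% of placements on the same side. Scores inside and outside regions were compared by their medians beside 10000 random sets of peaks of the same size. Regions were divided into 5 classes of equal size by width. Distances ran from the nearest end of a peak to the nearest end of a region, and clustering was counted midpoint to midpoint within 10 kb. Densities per Mb were correlated across chromosomes with Pearson's r and Spearman's rho and two-sided permutation tests of 100000 resamples, with Benjamini-Hochberg adjustment over 6 relations, and r was given again without the 2 chromosomes farthest from the median. Shares have exact Clopper-Pearson 95% intervals. Peaks are not replicates, so no p-value was computed over them. The random sets and the main placements treat peaks as independent, although peaks cluster. Counts of sets or placements that reach an observed value are therefore descriptions of these lists.

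The planned tests, their alternatives and the rule for naming peaks were fixed before the data were examined. The rule took the 5 highest-scoring HNF1b peaks inside H3K4me3 regions, the 5 highest-scoring outside, the 3 widest regions with and the 3 widest without an HNF1b peak, and the regions with the most peaks. Added after seeing the data were the classes of region score, the classes of peak score, the profile of strong blocks in steps of 100 bp up to 3000 bp from peak midpoints, and the comparison of H3K4me3 scores between chromosomes. Alternatives covered score thresholds of both lists, autosomes only, merged regions, other definitions of overlap, other random placements, other neighbour distances, a log10 scale for scores, 10 width classes and other measures of the added comparisons.

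The overlap procedure was tested on simulated data with 7421 peaks, in 10 runs each with 0%, 10% or 30% of peaks planted in H3K4me3 regions. It called an excess in 0, 10 and 10 of the runs, and observed shares averaged 1.64%, 11.4% and 31.0% where 1.67%, 11.5% and 31.2% were expected. Peaks not planted were placed by the same random procedure as the comparison, without clustering or assembly gaps. The runs therefore checked the calculation and not the rate of false calls in real data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

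The reference material at hand held no genome sequence or gene annotation of mm9. The planned assignment of peaks to transcription start sites and genes, the tests of gene lists, including genes of DCT transport and known HNF1b targets, and the search for the HNF1 motif were therefore not run, and no peak is assigned to a gene.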

Results

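Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in mpkDCT4a cells, an immortalised line of mouse distal convoluted tubule (DCT) cells. The distal convoluted tubule is a kidney segment that reabsorbs salt, and the series asked where in its genome the transcription factor HNF1b binds, with a view to the Kir4.1/Kir5.1 potassium channel of its basolateral membrane. The 3 samples were an HNF1b immunoprecipitate, an immunoprecipitate of histone H3 trimethylated at lysine 4 (H3K4me3, a mark found at promoters of active genes) and an input library, with 1 sample in each group. Peak lists on the mouse build mm9 were available for the 2 immunoprecipitates, and the input was not analysed here. There were no replicates, so the values below describe these 2 lists, and the read depth behind them is unknown. Intervals are exact 95% binomial intervals over peaks or regions and cover counting error only.

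The HNF1b list held 7421 narrow peaks with a median width of 209 bp and a range of 146 to 1227 bp. Their score from the peak caller, whose scale the deposited list does not state, had a median of 16.7 and ran from 3.28 to 243. The H3K4me3 list held 18811 broad regions with a median width of 1843 bp, and 34 of them were wider than 10 kb. Together they covered 38908.1 kb, with the regions on assembled chromosomes making up 1.46% of the assembled length. Region scores ran from 1 to 377 with a median of 148 and cannot be set against the HNF1b scores.

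The first comparison asked how many HNF1b peaks lay in H3K4me3 regions, which were not checked against annotated promoters. Of the 7421 HNF1b peaks, 1187 overlapped an H3K4me3 region by at least 1 bp, a share of 16.0% (95% interval 15.2 to 16.8%). When the peaks were placed at random on their own chromosomes 1000 times, the mean share was 1.66% and the highest was 2.16%, so the observed share was 9.62 times the mean. With peaks placed only within windows of 1 Mb this ratio was 6.68. The other 6234 peaks, or 84.0%, lay outside H3K4me3 regions. Seen from the regions, 1135 of 18811 (6.03%, interval 5.70 to 6.38%) held an HNF1b peak, of which 1086 held 1 peak, 46 held 2 and 3 held 3. The share depended on which H3K4me3 regions were counted: against the higher-scoring 50% of regions it was 4.77%, or 4.01 times the random mean.

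The 5 highest-scoring HNF1b peaks inside H3K4me3 regions lay on chromosomes 2, 13 and 7. The peak with the highest score of the list, 243, spanned 26337569 to 26338099 on chromosome 2, within a region of 2279 bp whose own score was 11. A peak on chromosome 13 at 4190128 to 4190496 scored 241 in a region of score 12, and a neighbour on the same chromosome at 4232690 to 4233077 scored 220 at the edge of a region of score 9. A peak on chromosome 2 at 35070509 to 35070862 scored 223 in a region of score 30. The peak on chromosome 7 at 148402201 to 148402614, also with a score of 223, was the exception among these 5, in a region of 4007 bp with a score of 190. The regions holding 3 peaks each were on chromosome 11 at 101487914 to 101491897, on chromosome 13 at 98781333 to 98787536 and on chromosome 3 at 96287548 to 96293793.

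HNF1b peaks in H3K4me3 regions had higher scores than peaks elsewhere. The median score was 26.5 (interquartile range 14.8 to 50.7) inside the regions and 15.9 (11.6 to 23.8) outside, a difference of 10.6 that was 3.67 when only the higher-scoring 50% of H3K4me3 regions were counted. Among 10000 random sets of peaks of the same size as the full overlapping set, differences ran from -1.83 to 2.04 and 0 were as far from zero. Peaks inside regions were also wider, with medians of 253 and 204 bp. Divided by score into 10 classes of equal size, the class with the highest scores had 361 of 742 peaks in an H3K4me3 region, or 48.7% (45.0 to 52.3%). The next class had 21.3%, and the second to seventh classes lay between 7.68% and 11.9%. The class with the lowest scores had 13.3%, above the 8.49% of the class next to it, and their 95% intervals narrowly failed to meet. The peaks had 902 distinct scores, and tied peaks at a class border were divided by their order along the genome. Whether this narrow contrast depends on that division was not tested.

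**Figure D1:**
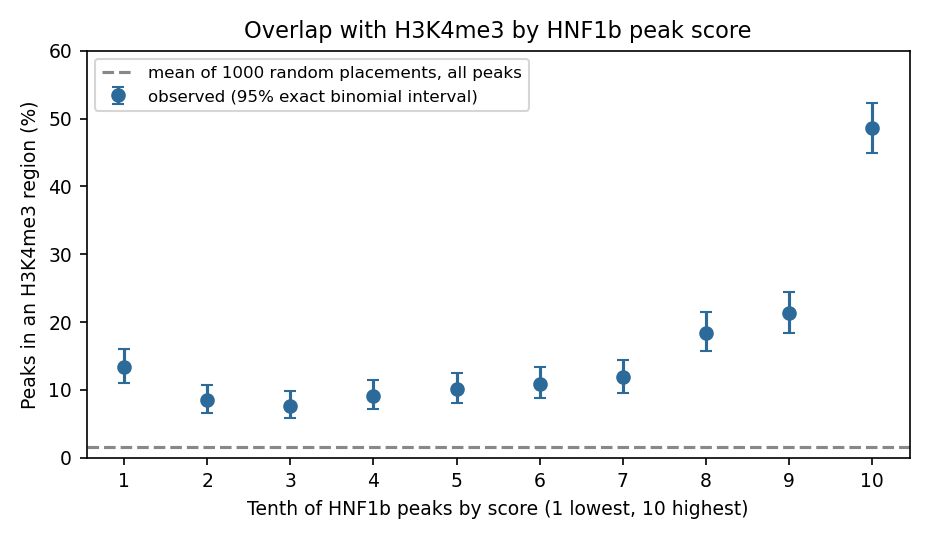
Share of HNF1b peaks that overlap an H3K4me3 region (vertical axis, %) for 10 classes of HNF1b peak score from lowest to highest (horizontal axis). Points are observed shares with exact 95% binomial intervals, and the dashed line is the mean of 1000 random placements of all peaks, 1.66%; the highest class stands at 48.7%.

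The high-scoring HNF1b peaks outside H3K4me3 regions included several far from any region. The highest, with a score of 168, lay on chromosome 14 at 46049725 to 46050132, 33082 bp from the nearest region. Of the 2 on chromosome X, the peak at 91413593 to 91414819 (score 167) was the widest of the list at 1227 bp and lay 7196 bp from a region, and the peak at 15330784 to 15331153 (score 165) lay 276988 bp away. A peak on chromosome 12 at 28192739 to 28193060 scored 158 at a distance of 163746 bp. The last of these 5, on chromosome 17 at 26559335 to 26559695, scored 145 at 5812 bp.

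HNF1b peaks were also described by their distance to the nearest H3K4me3 region. Beyond the overlapping peaks, 331 (4.46%) lay up to 2.5 kb from a region, 759 (10.2%) between 2.5 and 10 kb and 2748 (37.0%) between 10 and 100 kb, and 2396 (32.3%, interval 31.2 to 33.4%) lay beyond 100 kb. Random placement put a mean of 50.2% of peaks beyond 100 kb and never fewer than 48.3%, so that this class held 0.643 times the random mean. That ratio was 0.326 for the highest-scoring 10% of peaks and 0.842 when peaks were placed only within windows of 1 Mb. The class from 10 to 100 kb was within the random range, at 1.02 times its mean. The class from 2.5 to 10 kb was 1.23 times its random mean of 8.31% and above the highest placement, 9.31%. Neither class was examined with placement within windows of 1 Mb or for subsets of peaks, so whether the 1.23 holds there is unknown. The class up to 2.5 kb was 1.30 times its random mean of 3.42%, but 0.942 times when peaks were placed only within windows of 1 Mb and 0.833 times for the highest-scoring 10% of peaks, and in neither case did it lie outside the central 95% of placements.

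**Figure D2:**
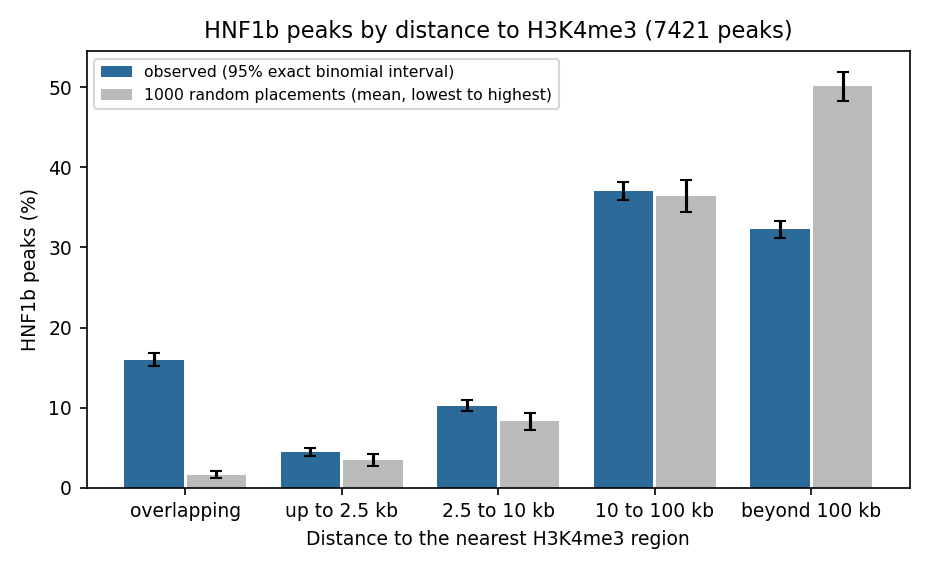
Share of the 7421 HNF1b peaks (vertical axis, %) by distance to the nearest H3K4me3 region (horizontal axis). Blue bars are observed shares with exact 95% binomial intervals and grey bars are means of 1000 random placements with their lowest and highest values; overlapping peaks make up 16.0% against 1.66%, and peaks beyond 100 kb 32.3% against 50.2%.

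HNF1b peaks also came in groups. Another HNF1b peak lay within 10 kb, midpoint to midpoint, of 846 peaks, or 11.4% (10.7 to 12.1%). Random placement gave a mean of 5.73% and at most 6.99%, a ratio of 1.99. For the highest-scoring 10% of peaks, with neighbours counted and placed among those peaks only, the ratio was 4.77. Fewer peaks give a lower random share, so this ratio does not mean that more of these peaks had a neighbour. For all peaks placed only within windows of 1 Mb the ratio was 1.56.

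The width of an H3K4me3 region did not set how often it held an HNF1b peak in a single direction. In 5 width classes of equal size, from narrowest to widest, 5.42%, 8.51%, 4.89%, 3.91% and 7.44% of regions held a peak. Random placement, in which wide regions are hit more often, gave means of 0.193%, 0.378%, 0.578%, 0.785% and 1.33%. The ratio of observed to random was therefore 28.1 in the narrowest class and 5.61 in the widest. The higher-scoring 50% of regions were also divided anew into 5 width classes. There the ratio was 1.90 in the narrowest and 5.91 in the widest, but these classes need not span the same widths as those above. In the full list the median region score was 11 in the narrowest class and 263 in the widest. The widest region of the list, 45871 bp on chromosome 11 at 96136774 to 96182644, held 1 peak, as did those of 33510 bp on chromosome 6 at 52157705 to 52191214 and of 16867 bp on chromosome 16 at 4591983 to 4608849. The widest regions with none were 30324 bp on chromosome 2 at 74524226 to 74554549, 26057 bp on chromosome 15 at 102788714 to 102814770 and 16603 bp on chromosome 13 at 40817522 to 40834124.

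Grouped by score instead, a comparison added after the scores of the overlapped regions had been seen, the regions with the lowest H3K4me3 scores held HNF1b peaks most often. In the class of lowest score (1 to 14), 487 of 3763 regions held a peak, or 12.9% (11.9 to 14.1%), which was 46.2 times the random mean of 0.280%. This ratio was 16.1 when peaks within 1 kb were counted, 32.2 with placement within windows of 1 Mb and 142 for the highest-scoring 10% of peaks. The share was 6.38% in the next class, 3.72% and 3.22% in the middle classes and 3.91% (3.31 to 4.58%) in the class of highest score (263 to 377), where the ratio was 3.42 (6.84 for the highest-scoring 10% of peaks and 2.44 with placement within windows of 1 Mb). The lowest class contributed 503 of the 1187 overlapping peaks, or 42.4% (39.5 to 45.2%).

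**Figure D3:**
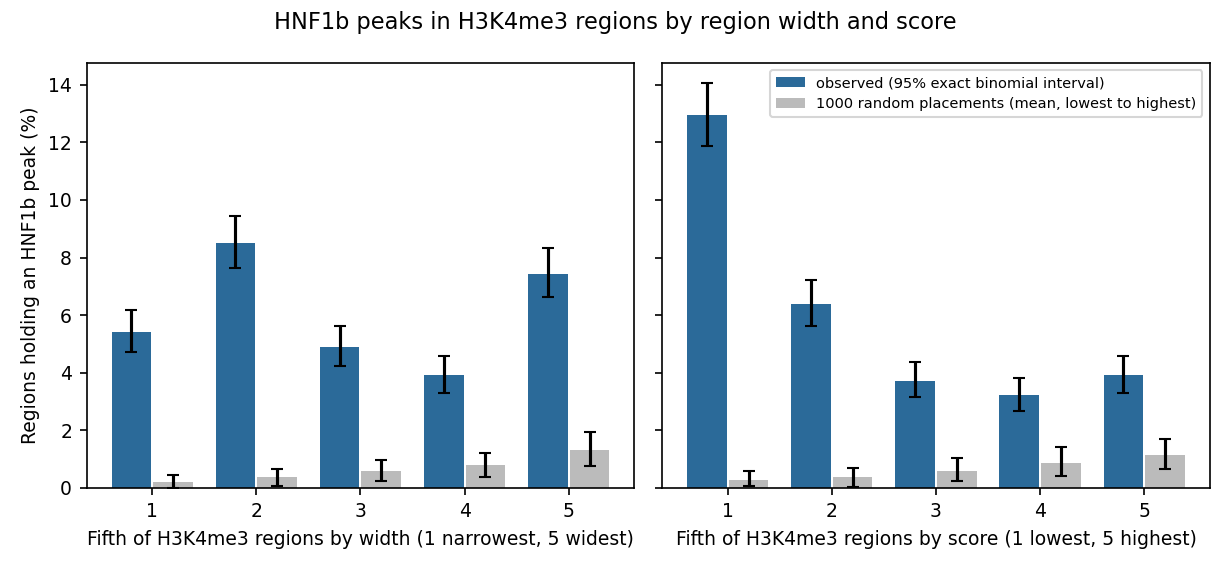
Share of H3K4me3 regions that hold an HNF1b peak (vertical axis, %) in 5 classes of region width (left) and of region score (right). Blue bars are observed shares with exact 95% binomial intervals and grey bars are means of 1000 random placements with their lowest and highest values; the class of lowest score stands at 12.9% and the class of highest score at 3.91%.

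Within the H3K4me3 regions the peak caller also marked 24709 strong blocks, and their position around HNF1b midpoints was described after the lists had been examined. For the 742 highest-scoring HNF1b peaks, a block covered the midpoint itself in 20.6% (17.8 to 23.7%). At 200 bp to either side the share was 31.9% (28.6 to 35.4%) and 31.8% (28.5 to 35.3%), so the midpoint had 0.647 times the share of its flanks. The flanks at 200 bp were chosen after the profile had been seen and are its highest points. Against flanks at 500 bp the ratio was 0.987, with overlapping intervals. Over all 7421 peaks the shares were 8.03% at the midpoint and 10.4% and 10.1% at the flanks. For the 3710 lower-scoring peaks the midpoint, at 5.63%, had an interval that overlapped those of its flanks, at 6.33% and 6.28%. Midpoint and flanks were read on the same peaks, and no comparison paired by peak was made.

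**Figure D4:**
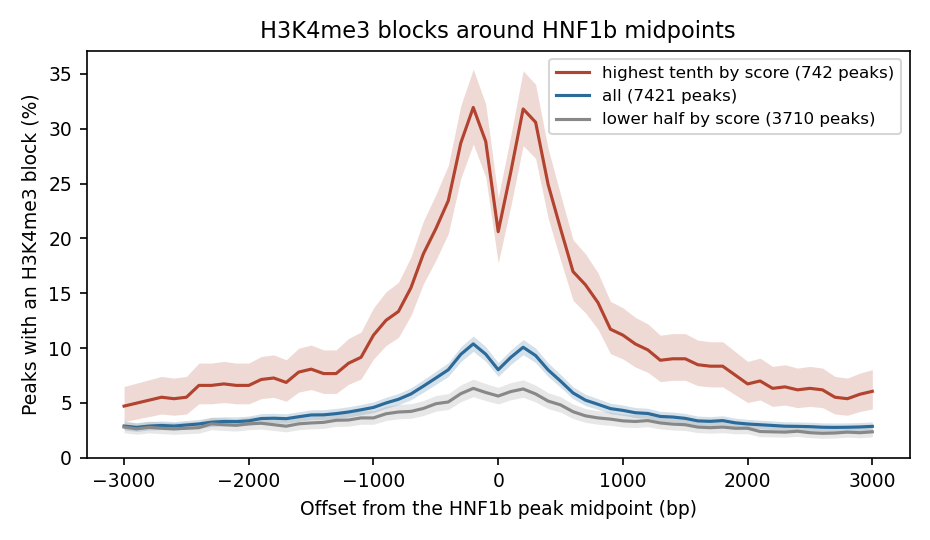
Share of HNF1b peaks with a strong H3K4me3 block (vertical axis, %) at offsets up to 3000 bp from the peak midpoint (horizontal axis, bp), for all peaks, the highest-scoring 742 and the lower-scoring 3710. Lines are observed shares and bands are exact 95% binomial intervals; the line of the highest-scoring peaks dips to 20.6% at the midpoint between flanks of about 32%.

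The density of HNF1b peaks differed between chromosomes. Chromosome 4 had 189 peaks (1.21 per Mb) and chromosome 7 had 223 (1.46 per Mb), against an autosome median of 2.96 per Mb with an SD of 0.696 over 19 autosomes. The highest densities were on chromosomes 11 (3.86 per Mb), 10 (3.85) and 19 (3.73). The H3K4me3 list did not share the low values, with 7.07 regions per Mb on chromosome 4 and 7.97 on chromosome 7 beside an autosome median of 7.29. On chromosome X, 465 HNF1b peaks gave 2.79 per Mb, but 8 of them, or 1.72% (0.746 to 3.36%), overlapped an H3K4me3 region, 2.48 times the random mean of 0.695%; this was above the central 95% of placements (up to 1.51%), and 10 of 1000 placements reached it. H3K4me3 regions on chromosome X stood at 3.24 per Mb. The highest overlap shares were 28.8% (23.0 to 35.2%) on chromosome 19 and 24.3% (20.4 to 28.4%) on chromosome 11, which also had the highest random means, 2.79% and 3.11%. Relative to random placement these shares were 10.3 and 7.79 times the mean, and the highest ratio was 15.6 on chromosome 1. Across all 21 chromosomes the densities of both lists were correlated, with a Pearson r of 0.632 (two-sided permutation p = 0.00376, Benjamini-Hochberg adjusted 0.00564) and a Spearman rho of 0.492 (permutation p = 0.0252, adjusted 0.0302), in a family of 6 relations. Without chromosomes 11 and Y, the farthest from the median, r was 0.211 (permutation p = 0.379), so the relation rested on those chromosomes. Over the 19 autosomes r was 0.399 (permutation p = 0.0901, adjusted 0.0901) and rho 0.398 (permutation p = 0.0928, adjusted 0.0928), and r was 0.0281 without chromosomes 11 and 19. Chromosomes are not replicates.

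**Figure D5:**
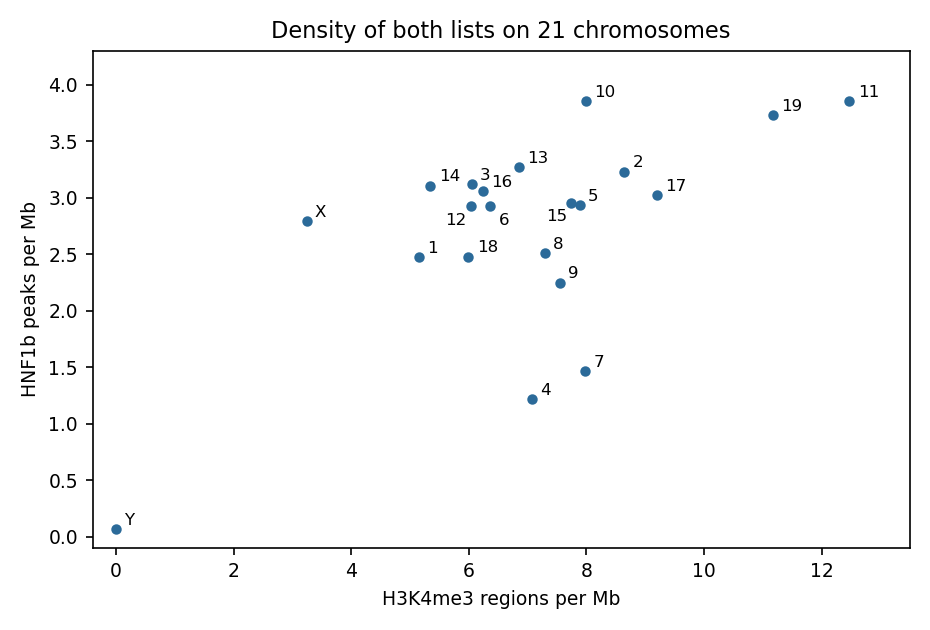
HNF1b peaks per Mb (vertical axis) against H3K4me3 regions per Mb (horizontal axis), 1 point for each of 21 assembled mouse chromosomes, labelled by name. Chromosomes 4 and 7 lie at 1.21 and 1.46 HNF1b peaks per Mb with H3K4me3 densities near the autosome median of 7.29.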

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

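Of 92 combinations of a result and an alternative setting, 78 kept their direction and their side of the threshold, or stayed inside the interval of the value reported; 68 of the combinations were planned and the others were chosen after seeing the data. The 78 include outcomes fixed in advance, since the observed share of overlapping peaks does not depend on how random peaks are placed. The share of HNF1b peaks in H3K4me3 regions, 16.0%, became 22.2% for the higher-scoring 50% of peaks, 48.7% for the highest-scoring 10%, 17.0% on autosomes, 4.77% against the higher-scoring 50% of regions, 14.8% both when at least 50% of the peak had to be covered and when its midpoint had to lie inside, and 17.9% within 1 kb. Its ratio to random placement stayed between 4.01 and 26.7. The difference in median HNF1b score between peaks inside and outside regions, 10.6, ranged from 3.67 against the higher-scoring 50% of regions to 13.9 for the highest-scoring 10% of peaks. The excess of peaks up to 2.5 kb from a region (1.30) fell to 1.14 for the higher-scoring 50% of peaks, inside the range of placement, and went below 1 for the highest-scoring 10% (0.833) and for placement within 1 Mb windows (0.942); the cause was not tested. The deficit beyond 100 kb stayed between 0.326 and 0.842 and clustering between 1.41 and 4.77. Ratios ranged from 1.90 to 65.0 in the narrowest regions, 4.27 to 14.4 in the widest, 16.1 to 142 in the lowest-scoring and 2.44 to 6.84 in the highest-scoring. Classes were formed anew for each set of regions, so the 1.90, from the higher-scoring 50% of regions, belongs to a different narrowest class. Each class was compared only with placement, never narrowest with widest. In the higher-scoring 50% of regions the narrowest class lay below the widest (1.90 against 5.91). This is the reverse of the full list (28.1 against 5.61), yet both ratios count among the 78. The correlation of densities over all chromosomes (rho 0.492) dropped below its threshold on autosomes alone (rho 0.398). The relation of H3K4me3 score to HNF1b density reversed when the median of 1 to 2 kb regions was the measure (rho -0.541). The dip of strong blocks at HNF1b midpoints (0.647) had overlapping intervals, not paired by peak, for the lower-scoring 50% of peaks (0.893) and with flanks at 500 bp (0.987), which lie beyond the dip. Shifting all peaks of a chromosome together was not run for clustering, since it fixes the outcome, and settings that need an mm9 annotation or sequence were not run. With 1 sample per group no replicate could be left out. No paired analysis was possible because each group has 1 sample. Unknown read depth limits what the absence of a peak can show.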

Other observations

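Among overlapping HNF1b peaks of the highest score class, H3K4me3 regions of low score were the most frequent. Of the 361 overlapping peaks in the class of highest HNF1b score, 172 (47.6%, exact 95% interval 42.4 to 52.9%) lay in regions of the lowest of 5 score classes and 35 (9.70%, 6.85 to 13.2%) in the highest. Of the 362 overlapping peaks in the 5 lower of 10 classes of HNF1b score, 121 (33.4%, 28.6 to 38.5%) lay in the lowest class and 66 (18.2%, 14.4 to 22.6%) in the highest. The tests of explanations in this part were chosen after the patterns had been seen, and the design has no group that tests a biological explanation.

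A first pattern was the frequency of HNF1b peaks in H3K4me3 regions of low score. Region width did not account for it, since in 5 of 5 width classes the lower-scoring 50% of regions held a peak more often, with intervals apart, from 8.61% against 1.17% in the third class to 9.04% against 5.85% in the widest. Carry-over of HNF1b library reads strong enough to form blocks would put strong H3K4me3 blocks on the peak midpoints. In the lowest score class 447 peaks had their midpoint inside a region. Of these midpoints 120 (26.8%, interval 22.8 to 31.2%) lay in a block, below every random draw of positions in the same regions (mean 38.1%, lowest 30.2%). In the next score class the share was 59.7%, within its random range of 51.7 to 73.9%. The higher classes were also within theirs, so the comparison goes against such carry-over only in the lowest class. Carry-over too weak to form a block was not tested, and this comparison is not independent of the dip of blocks at midpoints described above. A shared background of accessible promoters in both libraries stays open: the highest-scoring regions exceeded placement 3.42 times, but that value is part of the pattern and decides nothing. What kind of element the low-scoring regions are was not tested.

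A second pattern was the low density of HNF1b peaks on chromosomes 4 and 7. Fewer mappable or assembled bases would be expected to lower both lists. The lower of their H3K4me3 densities was 0.970 times the autosome median, so a loss in both lists was not seen. This cannot exclude it, because autosomes differed widely, from 5.15 regions per Mb on chromosome 1 to 12.5 on chromosome 11. The density expected for chromosomes 4 and 7 is therefore unknown. A lower DNA copy number of these chromosomes in the line is a candidate explanation: they had the 2 lowest 90th percentiles of H3K4me3 region score among autosomes (199 and 238, autosome median 296), and this percentile rose with HNF1b density (rho 0.7995, permutation p = 0.0001, Benjamini-Hochberg adjusted 0.00039; r 0.919, p = 1e-05, the smallest the permutations can give, adjusted 2e-05; r 0.819 without chromosomes 4 and 7). The percentile was chosen after medians of 1 to 2 kb regions had given the opposite sign (rho -0.541) and medians of 2 to 3 kb regions the same sign (rho 0.745), and a higher share of the 1 to 2 kb regions lay in the upper 3 score classes on chromosome 4 (70.8%) than on any other chromosome. Chromosome X goes against a simple rule, with a percentile of 177 and 2.79 HNF1b peaks per Mb, and the input library, which could decide on copy number, was not analysed here.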
